A study of Homo sapiens with 6 samples.

How the data were processed

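Polyadenylated RNA was sequenced from A172 cells, a human glioblastoma line, in 6 libraries of 3 groups. Per the labels' protocols, cells received a control microRNA, a miR-324-5p duplex (5p duplex) or a miR-324-3p.1 duplex (3p.1 duplex) by lipid transfection and were harvested after 1 day. Each group held 2 libraries, and group and replicate number were taken from the labels. RNA was enriched with oligo-dT, made into stranded libraries and read as 100 bp pairs on a DNA nanoball sequencer, per the labels' protocols. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples.

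The authors deposited 1 list of gene symbols with TPM (a unit scaled by transcript length and library size) for each library. RSEM and the GRCh38 assembly are named per the submitters' processing notes; versions, the gene annotation and the aligner are not given in the sources used here. Values ran from 0.01 TPM upward and summed to the same total in each library, so sequencing depth is unknown, no count test was possible and no counting interval is given. Between 18660 and 19070 symbols were listed per library. A symbol that was not listed in a library was taken as 0, and the 21 to 23 symbols listed more than once in a library were summed. No mitochondrially encoded gene appeared under the symbols searched, so that list of 13 genes could not be tested.

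Expression was analysed as log2(TPM + 1), which understates the change of low genes. Genes with a mean of at least 1 TPM over the 6 libraries were kept (13400 of 20979 symbols). One linear model of group means was fitted to all 6 libraries with limma 3.58.1 in R 4.3.3 (moderated variances with a trend on mean expression, 3 residual and 3.38 prior degrees of freedom), and genes with a Benjamini-Hochberg adjusted p under 0.05, two-sided, were called changed. All adjusted p-values of single genes come from this limma model. With 2 libraries per group an exact permutation test of 1 gene cannot go below p = 0.333, so none was used for single genes. Errors of log2 fold changes are standard errors from the model, and errors of TPM means are standard deviations (SD) of 2 libraries.

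Gene lists were tested with camera in limma at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry beside it, adjusted over the lists of a contrast. The 25 lists covered reported targets of miR-324-5p and of miR-324-3p (both recalled from the literature, not a database), Hedgehog and Wnt signalling, G1/S, G2/M, CDK inhibitors, p53 targets, interferon, NF-kB, integrated stress response, endoplasmic reticulum chaperones, cholesterol synthesis, hypoxia, extracellular matrix, TGF-beta and YAP targets, immediate early genes, the microRNA pathway, ribosomal proteins, mitochondrially encoded genes, oxidative phosphorylation, and glial, neuronal, epithelial and blood or endothelial markers. A list was tested where at least 5 members were expressed, which 22 lists met. With an estimated correlation the adjustment gave many lists the same adjusted p, as it did for many site classes. These adjusted values therefore do not rank the lists or classes.

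Gene symbols were matched to GENCODE 29 on GRCh38: 12611 by symbol, 337 by an older symbol, and 452 not at all. The longest annotated 3′UTR was used for the 11992 genes that had one (median 1379 nt). Sites were sought for 4 seeds in 4 classes: 8mer, 7mer-m8, 7mer-A1 and 6mer only. The MIR324 hairpin of 83 nt lies on chromosome 17 from 7223297 to 7223379 on the minus strand (GRCh38). The miR-324-5p sequence begins CGC at base 16 of the hairpin, which gives the site GGGATGC. The labels do not give the sequence of the 3p.1 duplex, so 3 starts of the 3p arm were tried, at bases 53, 51 and 50 of the hairpin, which give the sites GGGGCAG, GGCAGTG and GCAGTGG. Camera with the preset and with an estimated correlation was run over the 48 combinations of seed, class and contrast, adjusted together. All 7-mers found in at least 50 3′UTRs (16220) were ranked by the rank-sum z of log2 fold changes, once as they stood and once after a fit on 3′UTR length, GC content and mean expression. These z values describe genes and carry no p-value over samples. Shares of called genes with a site were set against other genes with Fisher's exact test and against 10000 draws matched on mean expression and 3′UTR length. Median log2 fold changes of genes with 8mer or 7mer-m8 sites were set against 10000 random lists matched on the same traits.

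Genes named in each contrast were the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 TPM and non-overlapping groups, up to 4 members of each list by adjusted p, the 10 genes with a 7mer or 8mer site that fell most, and SMO, GLI1, CREBBP, DVL2, TUT4, TUT7 and DICER1 whatever their values. GLI1 was below the expression minimum. The groups, the design, the lists, the seeds, the named-genes rule and the alternatives of pseudocount, filter, scaling, samples, replicate number, variance trend and left-out libraries were set before the data were examined. For the 3p.1 and control comparison, which shares its 2 control libraries with the 5p and control comparison, 50 simulations of unchanged groups gave the correlation that chance alone yields. Figures and sequence searches used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

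The procedure was tested on simulated data built on the 5p duplex and control comparison (13400 genes, 10 runs). It called 99.8% of genes lowered by 2 on the log2 scale, 91.4% of those lowered by 1 and 17% of those lowered by 0.5. Unchanged genes made up 6.4% of the calls. A list lowered by 0.1 was called in 100% of runs and an unchanged list in 0%. Simulated genes varied independently, so these rates do not apply to lists whose members vary together. The estimated correlation of the interferon list, for example, was 0.8703. The scan ranked a planted 7-mer with a drop of 0.1 at 1 among the 7-mers, on simulated fold changes of 11992 genes. Those fold changes were independent and had no link to 3′UTR length or GC content. In the data the SD of z was 3.59 uncorrected and 1.21 corrected (5p duplex against control), so that rank does not carry over.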

Results

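The series concerns the switch between the arms of a microRNA hairpin and its regulation by uridylation. These libraries measured the transcriptome of A172 glioblastoma cells after transfection of duplexes named for the arms of miR-324. Which strand of a duplex acted was not measured. Cells received a control microRNA, the 5p duplex or the 3p.1 duplex (n = 2 libraries each), and RNA was taken after 1 day. Between 13216 and 13536 genes per library reached 1 TPM, and the 10 most abundant genes held 6.15% to 7.17% of the TPM. Replicates of a group differed by a median of 0.167 (control), 0.153 (5p duplex) and 0.129 (3p.1 duplex) on the log2 scale. Log2 expression correlated across genes at 0.976 to 0.990 between libraries. Sequencing depth is unknown, since TPM keeps no read number.

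The first comparison, 5p duplex against control, asked which transcripts stood lower with the 5p duplex. VDAC1, which encodes the main channel of the outer mitochondrial membrane, fell from 579 ± 25.1 TPM in control (SD, n = 2) to 154 ± 7.13 TPM with the 5p duplex, a log2 fold change of -1.90 (SE 0.0897, adjusted p = 0.00256). PLPP1, a phospholipid phosphatase, fell from 34.7 ± 2.84 to 7.56 ± 0.311 TPM (log2 -2.06, SE 0.106, adjusted p = 0.0029). ASF1B, a histone chaperone, fell from 110 ± 16.2 to 19.9 ± 4.65 TPM, and LIPA, the lysosomal acid lipase, fell from 214 ± 55.5 to 51.6 ± 1.96 TPM (log2 -2.41 and -2.01). SCD, the stearoyl-CoA desaturase, fell from 518 ± 78.4 to 192 ± 12 TPM, the receptor tyrosine kinase AXL from 419 ± 53.4 to 182 ± 21.6 TPM, and the calcium-binding protein gene S100A16 from 793 ± 31.9 to 241 ± 59.6 TPM (n = 2 each). Of the rises other than the read-through transcript MINOS1-NBL1 and small RNA genes, which are given below, the kinase gene STK38L rose from 11.9 ± 0.226 to 25.6 ± 2.93 TPM (log2 1.04, adjusted p = 0.027), and LRIG1, which encodes a negative regulator of growth factor receptors, rose from 21.8 ± 2.04 to 40.1 ± 2.34 TPM (log2 0.85, adjusted p = 0.046). Both stood at similar levels with the 3p.1 duplex, as given below, so they do not mark the 5p duplex alone. In fits that left out 1 library, VDAC1 (-1.85 to -1.95) and PLPP1 (-1.98 to -2.14) kept their calls, ASF1B lost it without control replicate 2 (-2.26) or 5p duplex replicate 1 (-2.19), and LIPA without 5p duplex replicate 1 (-2.04) or 2 (-1.97). S100A16 kept its call only without control replicate 1 (-1.78) or 5p duplex replicate 2 (-1.99), SCD and AXL only without control replicate 1 (-1.58 and -1.33), and STK38L (0.93 to 1.16) and LRIG1 (0.76 to 0.94) in none of the 6 fits.

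In all, 62 of 13400 genes changed with the 5p duplex, 57 lower and 5 higher, and 38 of them changed at least 2-fold on the log2(TPM + 1) scale. At an unadjusted p under 0.05 there were 1227 genes, against 670 that chance would give. A fit with a term for replicate number, which the labels tie to no batch, called 367 genes. Groups of 2 did not overlap in 34.8% of genes, where chance gives 33.3%. C6orf62, a gene of unassigned function, and SYNGR2, which encodes a vesicle membrane protein, fell from 244 ± 17.2 to 92.2 ± 3.95 TPM and from 85.9 ± 1.07 to 31.2 ± 4.49 TPM (n = 2). The count moved with the libraries used: 128 genes without control replicate 1, 19 without control replicate 2, 7 and 28 without 5p duplex replicate 1 and 2, and 12 without either 3p.1 duplex library. Of the 62 genes, 37, 12, 4, 11, 12 and 12 remained in those fits, and the count was 9 with no filter on low values, 11 with only the 2 groups compared and 33 without a variance trend.

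Genes of small RNAs are reported as library values. They were not listed in whole groups, where they were taken as 0, and oligo-dT selection is not made for RNAs without a poly(A) tail. SNORA27 stood at 53.06 and 27.01 TPM in the controls and was not listed, so taken as 0, in the other 4 libraries. SNORA29 stood at 12.31 and 17.09 TPM and RNU4-1 at 9.87 and 6.93 TPM with the 5p duplex. Both were not listed elsewhere and were taken as 0 there. NBL1 and the read-through transcript MINOS1-NBL1 overlap, and their values are uncertain. NBL1 stood at 13.5 ± 0.368, 1.24 ± 1.16 and 2.38 ± 0.919 TPM in control, 5p duplex and 3p.1 duplex, and MINOS1-NBL1 at 0.70 ± 0.269, 6.82 ± 1.05 and 12.8 ± 3.27 TPM. Their sum was 14.2 ± 0.099, 8.06 ± 2.21 and 15.2 ± 2.35 TPM (n = 2 each).

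Sites for the miR-324-5p seed marked most of the fallers. Of 56 lowered genes with an annotated 3′UTR, 34 (60.7%) carried a 7mer or 8mer site matching GGGATGC, against 14.3% of other genes (Fisher's exact p = 2.0e-15, odds ratio 9.25), and 12 of them an 8mer. None of 10000 draws matched on expression and 3′UTR length reached that share, the highest being 32.1%. VDAC1 (chromosome 5, 133971915 to 134005133, minus strand, GRCh38) has an 8mer, GGGATGCA, in its 3′UTR at 133972676 to 133972683. PLPP1 has a pair of 7mer-A1 sites in its 3′UTR, at 55425132 to 55425138 and 55425071 to 55425077 of chromosome 5. ARF3, a small GTPase, has an 8mer at 48937516 to 48937523 of chromosome 12 and fell from 123 ± 9.08 to 48.5 ± 3.49 TPM (n = 2), and AGTRAP, an angiotensin receptor partner, has an 8mer at 11750667 to 11750674 of chromosome 1 and fell from 27 ± 2.99 to 8.54 ± 1.46 TPM. LIPA and C6orf62 carried 7mer-A1 sites and S100A16, SCD, SREBF2, AXL and SYNGR2 7mer-m8 sites, while ASF1B and XBP1 held no more than a 6mer. In fits that left out 1 library, ARF3 lost its call without control replicate 2 (-1.40) or either 5p duplex library (-1.26, -1.40), and AGTRAP in all (-1.40 to -1.72) but that without control replicate 1 (-1.45). SYNGR2 lost it without control replicate 2 (-1.43) or 5p duplex replicate 1 (-1.30), and C6orf62 without 5p duplex replicate 1 (-1.44).

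**Figure D1:**
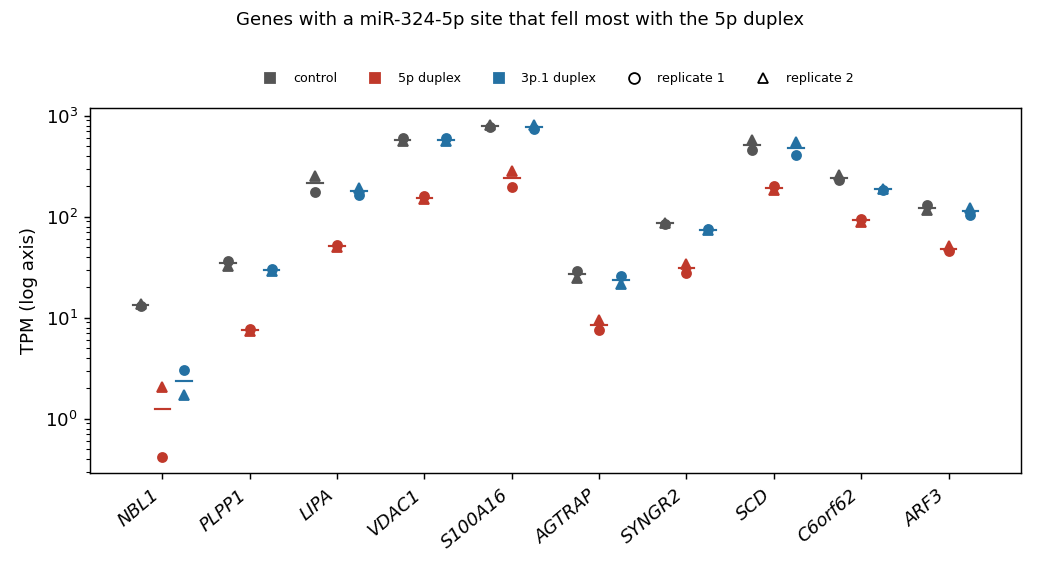
TPM (log axis) in each of the 6 libraries for the genes with a miR-324-5p site that fell most with the 5p duplex; colour gives the group and marker the replicate. VDAC1 stood at 579 ± 25.1 TPM in control, 154 ± 7.13 with the 5p duplex and 582 ± 32.2 with the 3p.1 duplex (SD, n = 2).

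Across the transcriptome, the 338 genes with an 8mer to GGGATGC had a median log2 fold change that differed by -0.115 from that of the 9010 genes without a site (camera adjusted p = 1.9e-08), and 76.0% of them lay below 0, against 55.3% without a site. The call was lost with an estimated correlation (adjusted p = 0.981 with an estimated correlation), and over 10 other alternatives the adjusted p ran from 1.6e-09 to 0.000674. With an estimated correlation the unadjusted camera p was 0.0568 for the 8mer and 0.171 for the 7mer-m8 class. Most site classes shared the adjusted value of 0.981. Relative to the control mean, the shift of the 8mer genes was -0.139 and -0.104 in the 5p duplex libraries. It was -0.053 and -0.0085 in the 3p.1 duplex libraries, with -0.0315 and 0.0315 in the controls. For the 727 genes with a 7mer-m8 the shift was -0.068 (adjusted p = 0.0035; adjusted p = 0.981 with an estimated correlation; 0.00194 to 0.126 over the other alternatives). That call was lost without control replicate 2 (-0.0498) and without 5p duplex replicate 1 (-0.0528). In the scan of 16220 7-mers, GGGATGC ranked 1 from the lowest, with z = -13.4 (SD of all z 3.59), and it ranked 1 again after correction for length, GC content and expression (z = -13.3, SD 1.21).

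**Figure D2:**
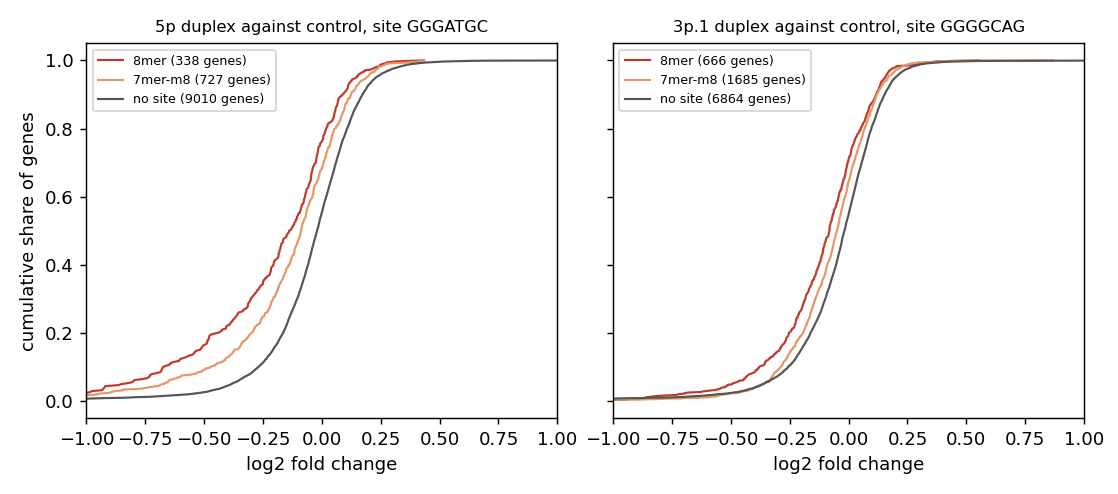
Cumulative share of genes against log2 fold change, in panels for each contrast and site, with a line for each site class. With the 5p duplex the 338 genes with an 8mer to GGGATGC lie left of the genes without a site, with a median difference of -0.115.

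A second word, GGCAGTG, was also low in this comparison. The 547 genes with its 8mer shifted by -0.046 (camera adjusted p = 0.0193; adjusted p = 0.981 with an estimated correlation; 0.00355 to 0.467 over the other alternatives). The shift was -0.0125 without control replicate 2 and -0.0486 without 5p duplex replicate 2, both no longer called, and -0.0853 without control replicate 1. In the scan GGCAGTG ranked 21 (z = -8.78), and 3 after correction (z = -9.20). Among lowered genes, 28 of 56 (50%) carried a site, against 30.9% of other genes (Fisher's exact p = 0.00336). SCD and ARF3 carried its 8mer beside their GGGATGC sites. Genes with GGGGCAG or GCAGTGG 8mers showed differences of -0.029 and -0.0065 (adjusted p = 0.873 and 0.936).

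Of the lists, interferon response genes stood lowest with the 5p duplex. All 37 measured members had negative log2 fold changes, with a median of -2.54 (camera adjusted p = 5.8e-35). The call was lost with an estimated correlation (adjusted p = 0.827 with an estimated correlation; 1.5e-72 to 0.827 over the alternatives without a term for replicate). The unadjusted camera p with an estimated correlation was 0.081. Over all genes 4 members fell, and 35 were lower when adjusted over the list alone. In a fit with a term for replicate number, 21 members fell over all genes. IFITM1, a membrane protein that restricts viruses, stood at 92.8 and 321 TPM in the controls and at 8.67 and 5.92 TPM with the 5p duplex (log2 -4.41, adjusted p = 0.0368). IFI6 and IFI27, both classical interferon-induced genes, and IRF9, a subunit of the interferon-activated transcription factor, had log2 fold changes of -3.37, -3.34 and -1.60 (adjusted p = 0.049, 0.049 and 0.0326). IFITM1 has close relatives that can share its reads, so its level is uncertain. The controls differed from each other: the median TPM of the list was 35.1 and 91.9 in control replicate 1 and 2, 10.2 and 7.32 with the 5p duplex, and 7.95 and 8.69 with the 3p.1 duplex. Without control replicate 2 the list's median was -1.49, with 6 members called lower over all genes, without control replicate 1, 34 members were called, and without any 1 of the 4 duplex libraries, 0.

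**Figure D3:**
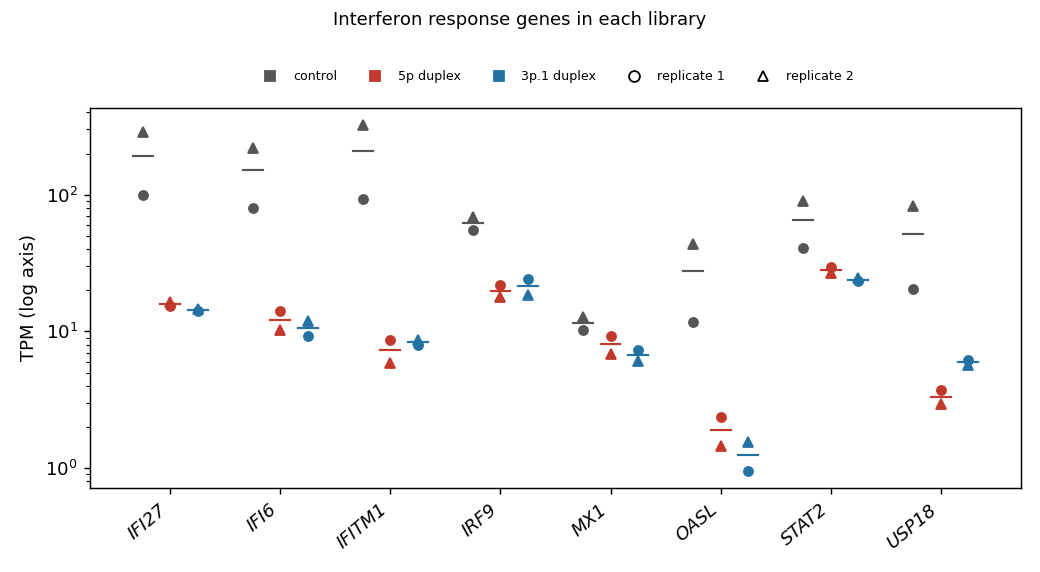
TPM (log axis) of interferon genes in each library; colour gives the group and marker the replicate. IFITM1 stood at 92.8 and 321 TPM in the controls, against 8.67 and 5.92 TPM with the 5p duplex.

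Cholesterol synthesis genes had a median log2 fold change of -0.19 with the 5p duplex (24 genes, 21 negative, camera adjusted p = 0.000357; adjusted p = 0.827 with an estimated correlation; 4.8e-05 to 0.827 over the alternatives without a term for replicate). SREBF2, the transcription factor that drives the pathway, fell from 30.2 ± 1.63 to 12.5 ± 0.127 TPM (n = 2, log2 -1.21, adjusted p = 0.019) and was the 1 member called over all genes. Of the fits that left out 1 library it kept that call without control replicate 1 (-1.26) and lost it in the other 5 (-1.15 to -1.22). Adjusted over the list alone 3 were lower: SREBF2, HMGCS1 and MSMO1, enzymes of the early and late pathway with log2 fold changes of -0.55 and -0.56 (adjusted p = 0.0967 and 0.170 over all genes). The list's median was -0.108 without control replicate 2, where the call was lost, -0.104 without 5p duplex replicate 1 and -0.293 without control replicate 1. SCD, another lipid gene outside the list, fell as given above.

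Targets of p53 had a median log2 fold change of 0.27 (28 genes, 23 positive, camera adjusted p = 2.6e-06; adjusted p = 0.827 with an estimated correlation; 7.2e-12 to 0.827 over the alternatives). No member changed by limma, over all genes or adjusted over the list alone. CDKN1A, the p21 inhibitor of the cell cycle, stood at 246 ± 80.5 TPM in control and 373 ± 36.4 TPM with the 5p duplex (n = 2, log2 0.63, adjusted p = 0.546), and BTG2, an antiproliferative gene, at 16.3 ± 5.34 and 27 ± 3.14 TPM (log2 0.72, adjusted p = 0.435). The median was 0.107, and no longer called, without control replicate 2, 0.452 without control replicate 1 and 0.176 without 5p duplex replicate 1. Ribosomal protein genes had a median of 0.11 (45 genes, 39 positive, camera adjusted p = 1.5e-05; adjusted p = 0.827 with an estimated correlation; 3.4e-14 to 0.870 over the alternatives), with RPS6 and RPL6 at log2 0.20 and 0.19 (adjusted p = 0.701 and 0.703). Their call was lost without control replicate 2 (0.0045), without 5p duplex replicate 1 (0.0599) and with quantile normalization (0.078), and the median was 0.224 without control replicate 1 and 0.174 without 5p duplex replicate 2. Ribosomal protein genes can share reads with processed pseudogenes, which was not measured, so single values are uncertain. Mitotic G2/M genes had a median of 0.079 (37 genes, 28 positive, camera adjusted p = 0.0158; adjusted p = 0.827 with an estimated correlation; 6.3e-06 to 0.962 over the alternatives), with HMMR, a spindle protein gene, at log2 0.27 (adjusted p = 0.519). That direction turned without control replicate 1 (-0.0748), the call was lost without 5p duplex replicate 2 (-0.0275) and with quantile normalization (0.0987), and the median was 0.233 without control replicate 2 and 0.190 without 5p duplex replicate 1. No member of either list was called over all genes or adjusted over the list alone. In every group the p53 and ribosomal medians were higher in replicate 1, and the G2/M median was higher in replicate 2. Fits without 1 library leave these replicate numbers unbalanced between the groups.

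Among the recalled targets of miR-324-5p, CUEDC2 fell from 127 ± 14.4 to 65.9 ± 0.495 TPM (n = 2, log2 -0.93, adjusted p = 0.0326) and carries an 8mer; the call stood without control replicate 1 (-0.81) and was lost in each of the other 5 fits that left out 1 library (-0.92 to -1.04). Of 7 measured targets it was the 1 that fell, and 2 were lower adjusted over the list alone, the other being FBXO11, a ubiquitin ligase subunit gene with an 8mer (log2 -0.40, adjusted p = 0.217); the list's median was -0.074 (camera adjusted p = 0.0776). SMO, the Hedgehog signal transducer, stood at 18.4 ± 1.08 and 17.4 ± 0.636 TPM (adjusted p = 0.898), and GLI3, a Hedgehog transcription factor with an 8mer, at 7.29 ± 0.431 and 4.96 ± 0.325 TPM (adjusted p = 0.254). The 8 measured Hedgehog genes had a median of -0.16 (adjusted p = 0.139), and none was called by limma, over all genes or adjusted over the list alone. CREBBP and DVL2, recalled targets of the 3p arm, had log2 fold changes of 0.066 and -0.27 (adjusted p = 0.911 and 0.703). The Wnt list had a median of -0.089 (23 genes, adjusted p = 0.660), with none called over all genes and BCL9 lower and PYGO2 higher adjusted over the list alone (log2 -0.87 and 0.44).

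Of the 22 lists tested, 5 were called with the 5p duplex, those above, against 0 with an estimated correlation and 0 by fry. XBP1, a transcription factor of the unfolded protein response, fell from 48.2 ± 8.22 to 22.5 ± 0.827 TPM (n = 2, log2 -1.06, adjusted p = 0.0499), the 1 member called among endoplasmic reticulum chaperones, over all genes and over the list alone. Its call stood without control replicate 1 (-1.23) and was lost in each of the other 5 fits that left out 1 library (-0.89 to -1.09). AXL was the 1 member called among TGF-beta and YAP targets over all genes, and adjusted over the list alone AXL was lower and ACTA2 (log2 0.61, adjusted p = 0.101 over all genes), a smooth muscle actin gene, higher. Over their lists alone RBL1 and CDKN1B (CDK inhibitors and RB family, log2 -0.73 and -0.43) and SPRY2 (immediate early genes, -0.76) were lower and CLDN4 (epithelial, 0.84) higher, with 0 called over all genes. Median log2 fold changes were -0.084 for G1/S, -0.040 for CDK inhibitors, -0.060 for NF-kB, 0.011 for the integrated stress response, 0.013 for chaperones and -0.010 for hypoxia (camera adjusted p = 0.0776, 0.742, 0.660, 0.493, 0.660 and 0.741). They were 0.038 for extracellular matrix, 0.056 for TGF-beta and YAP targets, -0.034 for immediate early genes, -0.017 for oxidative phosphorylation, 0.063 for glial and -0.049 for epithelial markers (camera adjusted p = 0.204, 0.493, 0.704, 0.660, 0.704 and 0.741). The recalled 3p targets had a median of 0.066 (adjusted p = 0.770). For the recalled 3p targets, chaperones, TGF-beta and YAP targets and glial markers the median was positive and the mean negative, and for hypoxia, oxidative phosphorylation and epithelial markers the median was negative and the test pointed up. The 3 neuronal and 4 blood or endothelial markers measured were too few to test (medians -0.38 and 0.11).

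The second comparison, 3p.1 duplex against control, asked the same of the 3p.1 duplex. By limma 2 of 13400 genes changed, MINOS1-NBL1 higher and SNORA27 lower, the read-through transcript and the small RNA gene whose values are given above. At an unadjusted p under 0.05 there were 919 genes, against 670 by chance, and groups did not overlap in 36.3% of genes, where chance gives 33.3%. STK38L stood at 24.5 ± 0.714 TPM with the 3p.1 duplex and 11.9 ± 0.226 TPM in control (n = 2, log2 0.99, adjusted p = 0.117), and LRIG1 at 44.3 ± 1.82 and 21.8 ± 2.04 TPM (log2 0.99, adjusted p = 0.117). The count was 94 without control replicate 1, 6 without control replicate 2, 18 without either 5p duplex library, and 8 and 5 without 3p.1 duplex replicate 1 and 2. Of the 2 genes, 1 remained without control replicate 2 and 1 without 3p.1 duplex replicate 2, and both remained in the other 4 fits. It was 0 with no filter on low values, where 1444 genes had an unadjusted p under 0.05 by limma, and 18 with only the 2 groups compared. A fit with a term for replicate number, which the labels tie to no batch, called 30 genes.

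Genes with 8mer sites for the 3p seed that begins at base 53 of the hairpin stood lower with the 3p.1 duplex, and genes with 7mer-m8 sites did not pass. The 666 genes with an 8mer to GGGGCAG had a median log2 fold change that differed by -0.064 from that of 6864 genes without a site, with 70.7% below 0 against 54.8% (camera adjusted p = 0.0035; adjusted p = 0.981 with an estimated correlation; 0.00107 to 0.126 over the other alternatives). The call was lost without control replicate 2 (-0.0506) and without 3p.1 duplex replicate 1 (-0.0563). The shift was -0.0881 and -0.0563 in the 3p.1 duplex libraries and -0.0718 and 0.0128 in the 5p duplex libraries. For the 1685 genes with a 7mer-m8 the difference was -0.0319 (adjusted p = 0.462), against -0.0355 with the 5p duplex (adjusted p = 0.347). GGGGCAG ranked 1 of 16220 7-mers, with z = -10.2 as the data stood and -7.16 after correction. EI24, a gene of an endoplasmic reticulum protein with an 8mer, stood at 58.7 ± 0.594 TPM, against 106 ± 2.79 TPM in control (n = 2). TOMM20, the import receptor of the outer mitochondrial membrane, also with an 8mer, stood at 130 ± 2.52 against 209 ± 3.3 TPM (n = 2). Neither was called over all genes. Both were picked in the third comparison for lower values in these same 3p.1 duplex libraries, so they give no separate support. The 8mers to GGCAGTG, GCAGTGG and GGGATGC gave differences of -0.0125, -0.0098 and -0.0252 (adjusted p = 0.936, 0.936 and 0.462).

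**Figure D4:**
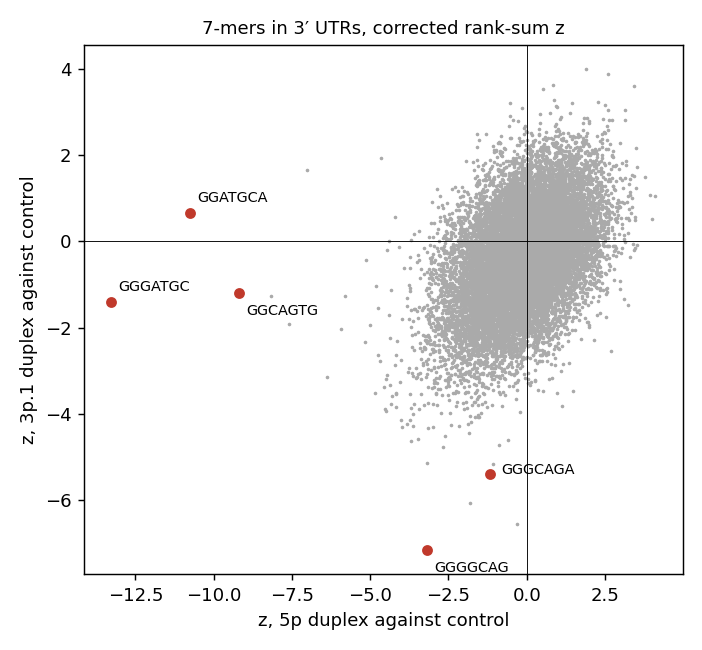
Corrected rank-sum z of each 7-mer in 3′UTRs, 5p duplex against control on the x axis and 3p.1 duplex against control on the y axis. GGGATGC lies lowest on the x axis (z = -13.3) and GGGGCAG lowest on the y axis (z = -7.16).

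Interferon response genes had a median log2 fold change of -2.50 with the 3p.1 duplex, negative in 37 of 37 (camera adjusted p = 9.8e-43; adjusted p = 0.851 with an estimated correlation; 4.6e-79 to 0.851 over the alternatives without a term for replicate). By limma 0 members passed over all genes and 35 were lower adjusted over the list alone; IFITM1 stood at a log2 fold change of -4.22 (adjusted p = 0.130) and IRF9 at -1.50 (adjusted p = 0.129). The median was -1.55 without control replicate 2, where 3 members were called over all genes, 34 were called without control replicate 1, and 0 without any 1 of the 4 duplex libraries. In a fit with a term for replicate number, 5 members were lower over all genes. As given above, the list's median TPM in the controls was 35.1 and 91.9.

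Proliferation lists stood higher with the 3p.1 duplex by small amounts. G2/M genes had a median of 0.15, positive in 37 of 37 (camera adjusted p = 3.3e-08; adjusted p = 0.851 with an estimated correlation; 5.5e-16 to 0.851 over the alternatives), with the mitotic kinase PLK1 at log2 0.28 and the kinesin gene KIF20A at 0.26 (adjusted p = 0.738 and 0.597). G1/S genes had a median of 0.092, positive in 31 of 40 (adjusted p = 1.7e-05; adjusted p = 0.851 with an estimated correlation; 6.6e-07 to 0.851 over the alternatives), with UHRF1, a reader of replicating DNA, at 0.32 and the helicase gene MCM2 at 0.27 (adjusted p = 0.472 and 0.589). No member of either was called by limma, over all genes or adjusted over the list alone. Both lists stood higher in replicate 2 than in replicate 1 in every group, and fits without 1 library leave the numbers unbalanced. G2/M was lost without control replicate 1 (-0.0256) and without 3p.1 duplex replicate 2 (0.0032), and stood at 0.299 without control replicate 2 and 0.307 without 3p.1 duplex replicate 1; G1/S was lost without control replicate 1 (0.0341) and stood at 0.158 without control replicate 2 and 0.0489 without 3p.1 duplex replicate 2. Ribosomal protein genes had a median of 0.075 (40 of 45 positive, adjusted p = 3.7e-05; adjusted p = 0.851 with an estimated correlation; 1.0e-13 to 0.851 over the alternatives), with RPS9 at 0.20 (adjusted p = 0.837) and 0 members called over all genes or adjusted over the list alone. Their direction turned without control replicate 2 (-0.0381), the call was lost without 3p.1 duplex replicate 1 (0.020) and with quantile normalization (0.0623), and the median was 0.178 without control replicate 1 and 0.136 without 3p.1 duplex replicate 2.

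Recalled targets of the 3p arm did not pass with the 3p.1 duplex. The 5 measured genes had a median of -0.062 (camera adjusted p = 0.747), and 0 were called by limma over all genes or adjusted over the list alone. CREBBP, a histone acetyltransferase, stood at 24.5 ± 1.38 TPM against 25.1 ± 2.19 TPM in control, and DVL2, a Wnt transducer, at 24.5 ± 3.8 against 28 ± 4.79 TPM (n = 2, adjusted p = 0.989 and 0.918). ZCCHC11 (TUT4), a terminal uridylyltransferase whose 3′UTR carries an 8mer to GGGGCAG, stood at 24.2 ± 0.361 and 22.9 ± 2.66 TPM (adjusted p = 0.967), ZCCHC6 (TUT7) at 18.7 ± 0.424 and 19.9 ± 2.21 TPM (adjusted p = 0.958), and DICER1, the nuclease that cuts the hairpin, at 24.4 ± 2.04 and 22.3 ± 3.72 TPM (adjusted p = 0.944). The microRNA pathway list had medians of 0.050 with the 5p duplex and -0.066 with the 3p.1 duplex (21 genes, adjusted p = 0.455 and 0.658).

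With the 3p.1 duplex 4 of 22 lists were called, those above, against 0 with an estimated correlation and 0 by fry. Cholesterol synthesis genes had a median of -0.10, with 21 of 24 negative (camera adjusted p = 0.0513), and SREBF2 stood at 25.7 ± 2.65 TPM against 30.2 ± 1.63 TPM in control (n = 2, adjusted p = 0.779). Targets of p53 had a median of -0.060 while their test pointed up (camera adjusted p = 0.948). Relative to the control mean, the list's median was 0.1415 and -0.1415 in control replicate 1 and 2. It was 0.0853 and -0.1777 in 3p.1 duplex replicate 1 and 2. Fits without 1 library leave these replicate numbers unbalanced between the groups. The list was called downward without control replicate 2 (-0.172) or 3p.1 duplex replicate 1 (-0.178) and upward without control replicate 1 (0.0872) or 3p.1 duplex replicate 2 (0.0853). The test pointed up also for the Wnt, extracellular matrix and glial lists, with medians of -0.034, -0.0036 and -0.069 (adjusted p = 0.658, 0.191 and 0.948). CD68, a macrophage marker in the blood and endothelial list, was lower adjusted over that list alone (log2 -0.56).

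Both duplex groups were compared with the same 2 controls, so their fold changes share chance values. The overlap of calls was 2 genes, MINOS1-NBL1 (higher in both) and SNORA27 (lower in both), against 0.02 and 0.04 in simulations of unchanged groups and 0.000373 and 0.00425 for independent lists. Log2 fold changes correlated across genes at 0.556, against 0.502 ± 0.029 in the simulations, and their covariance was 0.0498, against 0.0194 ± 0.0017. The same sign was seen in 65.9% of genes, against 66.6% in the simulations. The simulations share the controls too, with a variance pooled over the groups, and the observed covariance lay 0.0304 above theirs. They drew each gene independently and without a term for replicate number. They therefore cannot yield unlisted genes or values exchanged between overlapping genes, as for SNORA27 and MINOS1-NBL1. The 2 shared calls give no measure of an effect common to both duplexes. The 37 interferon genes, with mean log2 fold changes of -2.45 (5p duplex) and -2.44 (3p.1 duplex), add to the observed covariance. How much of its excess they make up was not computed, so it is not shown to span the transcriptome. The controls were not split, since each part would hold 1 library, so part of the excess in calls and covariance is open to their shared values. Genes are not independent replicates.

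The third comparison set the 2 duplexes against each other, in the same fit to all 6 libraries. VDAC1 was lower with the 5p duplex than with the 3p.1 duplex, 154 ± 7.13 against 582 ± 32.2 TPM (n = 2, log2 -1.91, SE 0.0897, adjusted p = 0.00256), as was PLPP1, 7.56 ± 0.311 against 29.9 ± 0.933 TPM (log2 -1.85, adjusted p = 0.00561). GPD2, the mitochondrial glycerol phosphate dehydrogenase, was lower at 13.2 ± 1.07 against 33.4 ± 3.42 TPM (log2 -1.27, adjusted p = 0.0227), and AXL, LIPA and ASF1B were lower by log2 fold changes of -1.30, -1.77 and -2.13. In the other direction, EI24 was higher with the 5p duplex, 115 ± 4.62 against 58.7 ± 0.594 TPM (log2 0.95, adjusted p = 0.0227), as was TOMM20, 254 ± 32.2 against 130 ± 2.52 TPM (log2 0.95, adjusted p = 0.0325). CNOT6, a subunit of the deadenylase complex, and CLDN4, a tight junction gene, were higher by 0.90 and 1.08. In fits that left out 1 library, VDAC1 kept its call (-1.85 to -1.96) and PLPP1 lost it without 5p duplex replicate 1 (-1.89). EI24 (0.91 to 0.99), AXL (-1.18 to -1.43) and LIPA (-1.66 to -1.88) lost theirs without any 1 of the 4 duplex libraries, ASF1B without 5p duplex replicate 1 (-1.90) or either 3p.1 duplex library (-2.29, -1.96), TOMM20 in all fits (0.82 to 0.97) but that without 5p duplex replicate 2 (1.08), and GPD2 (-1.17 to -1.37), CNOT6 (0.82 to 0.98) and CLDN4 (0.92 to 1.24) in all 6.

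By limma 58 genes differed, 47 lower and 11 higher with the 5p duplex, and 25 of them at least 2-fold. At an unadjusted p under 0.05 there were 1252 genes, and groups did not overlap in 40.4%, where chance gives 33.3%. Of 46 lower genes with a 3′UTR, 32 (69.6%) carried a GGGATGC site, against 14.3% of others (Fisher's exact p = 3.7e-17). Of 8 higher genes with a 3′UTR, 6 (75%) carried a GGGGCAG site, against 27.9% (Fisher's exact p = 0.00764), and 39 of 10000 matched draws reached that share. A site for another 3p start, GCAGTGG, was as frequent among the higher genes (6 of 8, 75%, against 32%, Fisher's exact p = 0.016). GGGGCAG sites were also more frequent among the lower genes (19 of 46, 41.3%, against 27.9%, Fisher's exact p = 0.0483). So were GGCAGTG sites (24 of 46, 52.2%, against 30.9%, Fisher's exact p = 0.00345). The 6 with GGGGCAG were EI24, TOMM20 and SDF2 with 8mers, CNOT6 with a 7mer-m8 and TMEM64 and CLDN4 with 7mer-A1 sites; TVP23B, whose paralogue TVP23C can share its reads, and FRMD5 had no 7mer or 8mer. VDAC1, TOMM20 and other genes with processed pseudogenes can share reads with these copies, which was not measured, so their absolute levels are uncertain. SNORA31 stood at 91.68 and 20.02 TPM with the 3p.1 duplex and was not listed, so taken as 0, in the other libraries. The count was 19 without either control library, 7 and 26 without 5p duplex replicate 1 and 2, and 10 and 8 without 3p.1 duplex replicate 1 and 2; of the 58 genes, 17, 17, 4, 9, 5 and 5 remained. It was 5 with no filter on low values, 19 with only the 2 groups compared and 5 without a variance trend. A fit with a term for replicate number, which the labels tie to no batch, called 278 genes.

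Genes with an 8mer to GGGATGC differed by -0.088 between the duplexes (338 genes, camera adjusted p = 1.4e-06; adjusted p = 0.981 with an estimated correlation; 2.3e-07 to 8.8e-05 over the other alternatives). With a 7mer-m8 the difference was -0.057 (727 genes, adjusted p = 0.0107; adjusted p = 0.981 with an estimated correlation; 0.00441 to 0.135 over the other alternatives), and the call was lost without 5p duplex replicate 1 (-0.0322) and without 3p.1 duplex replicate 2 (-0.0457). The 666 genes with an 8mer to GGGGCAG stood at 0.032 (camera adjusted p = 0.214), which was not called. Their median was 0.0293, against 0.0129 in random lists matched on expression and 3′UTR length. For GGGATGC the medians were -0.0803 (8mer) and -0.049 (7mer-m8), against 0.0161 and 0.013 in matched lists. GGGATGC ranked 1 of 16220 7-mers from the lowest (z = -11.5), and again after correction (z = -12.4). GGGGCAG ranked 6134 (z = 1.5), and 16141 after correction (z = 3.03). GGCAGTG ranked 3 (z = -6.90), and 4 after correction (z = -7.78). The 547 genes with its 8mer were not called (-0.033, adjusted p = 0.0938).

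G1/S genes were lower with the 5p duplex than with the 3p.1 duplex, with a median of -0.20 and 36 of 40 negative (camera adjusted p = 1.6e-08; adjusted p = 0.995 with an estimated correlation; 2.6e-10 to 0.995 over the alternatives). MCM5, a subunit of the replicative helicase, stood at 43.8 ± 1.25 and 55.8 ± 3.38 TPM (n = 2, log2 -0.34, adjusted p = 0.294), CDT1, a licensing factor, at 13.3 ± 2.15 and 19 ± 0.983 TPM (log2 -0.49, adjusted p = 0.304), and 0 members passed by limma, over all genes or adjusted over the list alone. Targets of p53 were higher, with a median of 0.29 and 23 of 28 positive (adjusted p = 2.6e-05; adjusted p = 0.995 with an estimated correlation; 5.3e-11 to 0.995 over the alternatives), with TP53INP1 at log2 1.22 and BTG2 at 1.12 (adjusted p = 0.186 and 0.211) and 0 called over all genes or adjusted over the list alone. The p53 call was lost without 3p.1 duplex replicate 2 (0.158). Recalled targets of miR-324-5p had a median of -0.22 (6 of 7 negative, adjusted p = 0.0124; adjusted p = 0.995 with an estimated correlation; 0.00844 to 0.995 over the alternatives). CUEDC2 was lower (log2 -0.99, adjusted p = 0.0292), the 1 member called over all genes and adjusted over the list alone, and the list's call was lost without 5p duplex replicate 2 (-0.145). CUEDC2 itself lost its call without any 1 of the 4 duplex libraries (-0.93 to -1.05). The interferon list, with a median of -0.040 and 20 of 37 negative, did not differ by the test (adjusted p = 0.985).

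Between the duplexes 3 of 22 lists were called, those above, against 0 with an estimated correlation and 0 by fry. Adjusted over their lists alone, MYC, EGR1 and SPRY2 among immediate early genes were lower with the 5p duplex (log2 -0.37, -0.63 and -0.85). Also lower were RBL1, an RB family gene, XBP1 among chaperones, AXL among TGF-beta and YAP targets and the keratin gene KRT18 among epithelial markers (log2 -0.84, -0.89, -1.30 and -0.44). Higher over their lists alone were ACTA2 among TGF-beta and YAP targets, CLDN4 among epithelial markers, which was also called over all genes, and CD68 among blood and endothelial markers (log2 0.78, 1.08 and 0.61). Cholesterol synthesis genes had a median of -0.077 (camera adjusted p = 0.108), with SREBF2 the 1 member lower over all genes (log2 -0.98, adjusted p = 0.0325); its call was lost in each of the 6 fits that left out 1 library (-0.88 to -1.08). Hedgehog genes had a median of -0.092 and Wnt genes of -0.054 (adjusted p = 0.422 each).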

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

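The tests without small RNA genes, with APPRIS principal transcripts and with an estimated correlation beside the replicate block were chosen only after the result was seen.

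The main limits are 2 libraries per group, no read depth and replicates of unstated origin. Sequencing depth is unknown, so the error of low values cannot be given, and log2(TPM + 1) understates the change of low genes. Among the named genes alone, called ones kept their call in 350 fits and lost it in 280. Other called genes were not in that count. Calls of all genes are given in the order 5p duplex against control, 3p.1 duplex against control, 5p against 3p.1 duplex. With a pseudocount of 0.1, 60 of 62, 2 of 2 and 57 of 58 remained. Without a filter on low values 8 of 62, 0 of 2 and 4 of 58 remained. Without a variance trend 33 of 62, 2 of 2 and 5 of 58 remained. Over the 87 counts, lists, site classes and scan ranks, with 1356 alternatives and no single genes, 1107 kept direction and side of the threshold, 54 lost a call, 45 gained one, 4 turned direction with a call on 1 side, and 146 moved otherwise. VDAC1 fell with the 5p duplex in all 14 alternatives and PLPP1 in all 14, as did VDAC1 against the 3p.1 duplex. The 8mer sites to GGGATGC kept their call in all fits that left out 1 library, with shifts of -0.103 to -0.150 against control and -0.0672 to -0.101 against the 3p.1 duplex. No called gene turned direction under any setting. The longest annotated 3′UTR, set beforehand as another choice beside canonical transcripts, is identical to what was used, since the annotation carries no canonical mark. With an estimated correlation and with fry the log2 fold changes are the same and the test differs by construction. Fold changes are also the same where only the 2 groups are compared, or where the left-out library belongs to the group outside a contrast. Changes in single-gene calls there come from the variance estimate and its degrees of freedom. For the other changes the cause was not tested, though fits without 1 library also unbalance the replicate numbers, as given below.

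Without a filter on low values 9, 0 and 5 genes changed (5p duplex against control, 3p.1 duplex against control, 5p against 3p.1 duplex), where more genes are tested. Medians there were, for the 5p duplex against control, -0.141 for Hedgehog and -0.084 for G1/S (newly called), and -0.0167 for NF-kB (uncalled, direction of the test turned). Medians for the 3p.1 duplex against control were -0.0036 for epithelial (uncalled, direction of the test turned). The 5p against 3p.1 duplex contrast gave -0.0181 for recalled 3p targets, 0.0802 for CDK inhibitors and 0.0296 for matrix (uncalled, direction of the test turned), and -0.0741 for G2/M (newly called). At a mean TPM of at least 5, where fewer genes are tested, 83, 2 and 58 genes changed, and medians were, for the 3p.1 duplex against control, -0.0566 for p53 (uncalled, direction of the test turned), and -0.100 for cholesterol (newly called). Between the duplexes the medians were -0.0409 for interferon and -0.0054 for hypoxia (uncalled, direction of the test turned).

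With median-of-ratios scaling 42, 2 and 54 genes changed, and medians were, for the 3p.1 duplex against control, -0.0182 for p53 and -0.0273 for glial (uncalled, direction of the test turned). Between the duplexes the medians were -0.0457 for interferon (uncalled, direction of the test turned). With quantile normalization 43, 2 and 43 genes changed, and medians were, for the 5p duplex against control, -0.0432 for G1/S (newly called), and 0.0987 for G2/M and 0.078 for ribosomal proteins (no longer called), and 0.0451 for chaperones, -0.0001 for hypoxia and -0.012 for oxidative phosphorylation (uncalled, direction of the test turned). Medians for the 3p.1 duplex against control were -0.0154 for p53, 0.0113 for hypoxia, 0.0037 for oxidative phosphorylation and 0 for glial (uncalled, direction of the test turned), and -0.091 for cholesterol (newly called), and 0.0623 for ribosomal proteins (no longer called). With a pseudocount of 0.1, 60, 3 and 57 genes changed.

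With only the 2 groups compared 11, 18 and 19 genes changed, where fewer samples set the variance, and medians were, for the 3p.1 duplex against control, -0.0689 for glial (uncalled, direction of the test turned). Between the duplexes the medians were -0.0741 for G2/M (newly called). Without a trend in the variance 33, 2 and 5 genes changed. Without small RNA genes 1 gene changed with the 3p.1 duplex.

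The libraries share only a replicate number, which the labels tie to no batch. Deviations from group means correlated between equal numbers at 0.265 (control and 5p duplex), 0.375 (control and 3p.1 duplex) and 0.383 (both duplexes), and principal component 1 separated the numbers. With a replicate block 367 (41 higher, 326 lower), 30 (5 and 25) and 278 (77 and 201) genes changed, every main call was kept, 21 and 5 interferon genes were lower against control (5p duplex, 3p.1 duplex), 5 lists were called for 5p against 3p.1 duplex, and 13 genes overlapped between both duplexes against control. Medians there were, for the 5p duplex against control, -0.084 for G1/S (newly called), and -0.0395 for CDK inhibitors (uncalled, direction of the test turned). Medians for the 3p.1 duplex against control were -0.0596 for p53 and -0.0689 for glial (uncalled, direction of the test turned), and 0.0924 for stress response and -0.100 for cholesterol (newly called). The 5p against 3p.1 duplex contrast gave -0.0741 for G2/M and -0.077 for cholesterol (newly called). Sites corrected for 3′UTR length and GC content gave the same values with the replicate block and without it, for 5p against 3p.1 duplex: -0.0417 for 8mer sites to GGCAGTG (newly called) and -0.0081 for those to GCAGTGG (direction of the test turned). With APPRIS principal transcripts GGCAGTG stood at -0.0437 there (newly called).

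With an estimated correlation in camera 0 lists were called in each contrast, by construction with unchanged medians: for the 5p duplex against control, 0.0788 for G2/M, 0.269 for p53, -2.54 for interferon, -0.190 for cholesterol and 0.105 for ribosomal proteins (no longer called). Medians for the 3p.1 duplex against control were 0.0918 for G1/S, 0.155 for G2/M, -2.5 for interferon and 0.0752 for ribosomal proteins (no longer called). The 5p against 3p.1 duplex contrast gave -0.217 for recalled 5p targets, -0.201 for G1/S and 0.289 for p53 (no longer called). With the replicate block beside the estimated correlation the lists called were again 0 in each contrast, with the same medians no longer called, and the direction of the test turned for CDK inhibitors with the 5p duplex (-0.0395) and for p53 (-0.0596) and glial markers (-0.0689) with the 3p.1 duplex. With fry 0 lists were called in each contrast, and medians were, for the 5p duplex against control, 0.0788 for G2/M, 0.269 for p53, -2.54 for interferon, -0.190 for cholesterol and 0.105 for ribosomal proteins (no longer called), and 0.0112 for stress response, 0.0131 for chaperones, -0.0103 for hypoxia, 0.0562 for TGF-beta and YAP, -0.017 for oxidative phosphorylation and 0.0627 for glial (uncalled, direction of the test turned). Medians for the 3p.1 duplex against control were -0.0335 for Wnt, -0.0596 for p53, 0.0586 for NF-kB, 0.001 for hypoxia and -0.0689 for glial (uncalled, direction of the test turned), and 0.0918 for G1/S, 0.155 for G2/M, -2.5 for interferon and 0.0752 for ribosomal proteins (no longer called). The 5p against 3p.1 duplex contrast gave -0.217 for recalled 5p targets, -0.201 for G1/S and 0.289 for p53 (no longer called), and 0.0556 for recalled 3p targets, 0.0802 for CDK inhibitors, -0.0404 for interferon and -0.0151 for hypoxia (uncalled, direction of the test turned).

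Each fit without 1 library leaves a group with a lone sample, which is assumed to vary like the other groups. It also leaves the replicate numbers unbalanced between groups. Relative to the control mean, G2/M medians in replicate 1 and 2 were -0.1601 and 0.1601 (control) and -0.0275 and 0.1899 (5p duplex). With the 3p.1 duplex they were 0.0032 and 0.3067. The turns in direction that end this paragraph lie on the side this imbalance gives. With 1 library left out, 7 to 128 genes and 3 to 7 lists were called for the 5p duplex against control. Medians there ranged from -0.215 to -0.0693 for recalled 5p targets, -0.195 to 0.0657 for recalled 3p targets, -0.166 to -0.0067 for G1/S, -0.0748 to 0.233 for G2/M, 0.107 to 0.452 for p53, -0.328 to 0.0254 for NF-kB, -0.0574 to 0.107 for chaperones, -0.293 to -0.104 for cholesterol and -0.0855 to 0.0193 for hypoxia. They ranged from -0.184 to 0.297 for matrix, -0.0211 to 0.116 for microRNA pathway, 0.0045 to 0.224 for ribosomal proteins, -0.069 to 0.0822 for oxidative phosphorylation, -0.210 to 0.029 for epithelial, -0.0718 to 0.0128 for 8mer sites to GGGGCAG, -0.0853 to -0.0125 for 8mer sites to GGCAGTG and -0.03 to 0.0373 for 8mer sites to GCAGTGG. With 1 library left out, 5 to 94 genes and 4 to 9 lists were called for the 3p.1 duplex against control. Medians there ranged from -0.189 to -0.0151 for recalled 3p targets, 0.0341 to 0.158 for G1/S, -0.0256 to 0.307 for G2/M, -0.178 to 0.0872 for p53, -0.306 to 0.238 for NF-kB, 0.0278 to 0.0924 for stress response, -0.0774 to 0.134 for chaperones, -0.223 to -0.0092 for cholesterol, -0.0115 to 0.0319 for hypoxia and -0.217 to 0.277 for matrix. They ranged from -0.113 to 0.0903 for immediate early genes, -0.0886 to -0.0429 for microRNA pathway, -0.0381 to 0.177 for ribosomal proteins, -0.0958 to 0.111 for oxidative phosphorylation, -0.131 to -0.0103 for glial, -0.200 to 0.004 for epithelial, -0.0628 to 0.0084 for 8mer sites to GGGATGC, -0.0881 to -0.0506 for 8mer sites to GGGGCAG, -0.0563 to 0.0281 for 8mer sites to GGCAGTG and -0.0429 to 0.0358 for 8mer sites to GCAGTGG. With 1 library left out, 7 to 26 genes and 3 to 6 lists were called for the 5p against 3p.1 duplex. Medians there ranged from -0.259 to -0.145 for recalled 5p targets, -0.0395 to 0.0931 for recalled 3p targets, -0.238 to 0.0958 for G2/M, -0.0138 to 0.0802 for CDK inhibitors, 0.158 to 0.410 for p53, -0.169 to 0.152 for interferon, -0.293 to 0.0408 for NF-kB, -0.0466 to -0.0039 for stress response and -0.200 to 0.0195 for cholesterol. They ranged from -0.0548 to 0.0415 for hypoxia, -0.210 to 0.230 for matrix, -0.179 to 0.0405 for immediate early genes, -0.0426 to 0.0914 for ribosomal proteins, -0.062 to 0.0711 for oxidative phosphorylation, -0.0263 to 0.140 for glial, -0.255 to 0.145 for epithelial, -0.0083 to 0.0668 for 8mer sites to GGGGCAG and -0.002 to 0.0311 for 8mer sites to GCAGTGG. The direction turned with a call for G2/M with the 5p duplex without control replicate 1 (-0.0748), for ribosomal proteins with the 3p.1 duplex without control replicate 2 (-0.0381), and for p53 with the 3p.1 duplex without control replicate 2 (-0.172) or 3p.1 duplex replicate 1 (-0.178).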

Other observations

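Of the tests below, those of miR-324-5p sites in the same 3′UTRs and of sites in the coding sequence or 5′UTR were written before their values were seen; the other tests were chosen only after the result was seen.

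Interferon genes stood lower in both duplex groups than in control. Control replicate 2 alone is excluded as the source, since control replicate 1 by itself lay 1.519 (log2) above the 4 duplex libraries in the median over the list. Scaling is excluded, since the median nearer to 0 was -2.4593 after median-of-ratios scaling. Direct sites in the 3′UTRs of most members are excluded. Of the 37 genes, 10.8% carried a GGGATGC site and 13.5% a GGGGCAG site, against 14.5% and 27.9% of other genes. Sites in a gene that regulates the list, or in the coding sequence or 5′UTR of its members, were not tested here. A response to the control duplex itself is a hypothesis that cannot be told from a loss in both duplex groups, which differed by -0.04 in the list's median, because no untransfected library was used here.

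Genes with GGCAGTG in the 3′UTR stood lower with the 5p duplex, and sites for miR-324-5p in the same 3′UTRs are excluded as the source: among 9010 genes without GGATGC the z of GGCAGTG was -7.81. Length and GC content are excluded, with z = -9.2 after correction. The hypothesis that the opposite strand of the 5p duplex acts through the seed CACUGCC stays open: GGCAGTG stood at rank 3 after correction in each 5p duplex library taken alone, but both scans use the same controls and the joint scan had already ranked it 21 of 16220, and 3 after correction. Between the duplexes, where no control enters the fold change, it ranked 3 (z = -6.90) and 4 after correction (z = -7.78). Shifts of its 8mer genes were -0.0331 and 0.0331 in the controls, against -0.0486 and -0.0566 with the 5p duplex. They were -0.0326 and -0.0024 with the 3p.1 duplex. The sequences of the duplexes are not given in the sources used here, and strand use was not measured.

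Of the genes lowered by the 5p duplex, 22 had a 3′UTR without a 7mer or 8mer site to miR-324-5p. Sites in the coding sequence or 5′UTR were found in 3 of them (13.6%), against 20.5% of other genes (Fisher's exact p = 0.599, odds ratio 0.613, confidence interval 0.116 to 2.09), which cannot tell whether such sites contribute. These genes had shorter bodies (median 1032 against 1502 nt), and 4 were interferon genes. ASF1B, XBP1 and HSPD1 were among them.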
